A study of Mus musculus with 18 samples.

How the data were processed

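RNA was measured in erythroblasts cultured from fetal livers of mouse embryos with a p53-null genotype, per the labels. Cells carried a control hairpin (Sc), anti-Tis7 hairpin 1 or anti-Tis7 hairpin 2, and were treated with tunicamycin at 2.5 µg/ml for 0, 4 or 8 h. Cells were grown with erythropoietin, stem cell factor and dexamethasone, per the labels' protocols. RNA was bound to oligo(dT) beads and copied from random hexamers, per the labels' protocols. The deposited values are raw counts per Ensembl gene, made by the authors from reads aligned with STAR to mm10 (GRCm38.p5), per the submitters' processing notes. The sources used here do not name the counting program, the annotation release or the strand setting. Genes that overlap an antisense neighbour, and families with near-identical copies such as the histone genes, are therefore uncertain.

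All 18 libraries entered the fit, as 9 groups of 2 libraries. The table held 52550 genes, and 52403 identifiers matched the mouse gene table (GENCODE, GRCm38), which gave gene names and coordinates. Library totals ran from 16540598 to 21325197 counts. Between the 2 libraries of a group, Pearson's r of log2 CPM across genes, which are not independent replicates, ran from 0.9802 to 0.992. Counts of the same genes in the 2 libraries of a group differed by 11 to 41.1 in chi-square per degree of freedom, above sampling noise in each group. Libraries of different groups were not compared in this way.

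The comparisons, tests, gene lists, rule for named genes and alternatives were fixed before the data were examined, except where the text says otherwise. Genes were filtered with filterByExpr on the 9 groups (minimum count 10, minimum total 15), which kept 12823 genes, 12813 of them with a gene name. Libraries were scaled with TMM in edgeR 4.0.16 under R 4.3.3. Each gene was fitted with 1 mean per group and edgeR's robust quasi-likelihood test, with 9 residual degrees of freedom, and p was adjusted by Benjamini-Hochberg over the tested genes at 0.05. Standard errors were taken from the fold change and the F statistic. Intervals for Ifrd1 are 95% t intervals of the same fit. Comparisons were tunicamycin at 4 h and 8 h against 0 h and at 8 h against 4 h in control cells, knockdown (the mean of both hairpins) against control at each time and averaged over times, each hairpin against control and against the other, and the difference of the 4 h and 8 h responses between knockdown and control.

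The text always names Ifrd1, Ifrd2 and Trp53. For each comparison it draws on the 8 largest rises and 8 largest falls among genes past the threshold with a mean log2 CPM of at least 3, a known gene symbol and every library of one side above every library of the other. For averaged comparisons that had to hold at each of the 3 times, and it did not apply to the differences of responses. From each described list it names up to 4 members with the smallest p.

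The 24 gene lists fixed beforehand were tested with camera in limma 3.58.1 on log2 CPM, with a preset correlation of 0.01 and, as an alternative, an estimated one. P-values were adjusted over the lists of a comparison. Of 288 tests 104 passed with the preset and 10 with the estimated correlation. A list's median, mean and test differed in sign in 38 of the 288, none of which passed. Later, 6 lists were added after the data had been seen.

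Matches to 7-nucleotide windows of the hairpin targets were searched in annotated 3′ UTRs of at least 50 nucleotides in 10904 tested protein-coding genes other than Ifrd1, with Biostrings 2.70.1. Log2 fold changes were centred on their median, limited to 2 in size and cleared of their trend with 3′ UTR length and GC content. For each of 14157 7-mers held by at least 200 genes, the effect was the mean of genes with the 7-mer minus that of genes without, and z was this effect over its standard error. Each of these settings was tried at 1 value. Lists of 10 tissues were used for transcripts of other tissues. In the 4 libraries named in the text, the silent or nearly silent markers stood at 31.3 CPM for kidney, 27 for photoreceptors, 10.7 for muscle, 2.4 for other retinal cells, 2.27 for brain, 1.05 for liver, 0.912 for bone and cartilage, 0.283 for testis, 0.252 for pancreas and gut and 0.195 for adipose tissue.

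Alternatives were the Wald test of DESeq2 1.42.0, its size factors in edgeR, no filter on low counts, the replicate letter as a block, only the compared groups in the fit, and each library left out in turn. Later added were the omission of 4 libraries and the count over genes without GCAGACA or TGCAGAC in the 3′ UTR. Shared controls were simulated 20 times. Averaged comparisons were refitted on 100 splits of the libraries, the real one included.

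The procedure was tested on simulated counts of the 12823 genes with 200 changed genes. For knockdown against control averaged over times edgeR recovered 86.6% of genes changed 1.5-fold, 98.5% at 2-fold and 100% at 4-fold, with 12 false calls, and DESeq2 recovered 88.1%, 98.5% and 100%, with 31. For tunicamycin at 8 h in control cells edgeR recovered 32.8%, 79.1% and 100%, and for the difference of the 8 h responses 10.4%, 58.2% and 95.5%. For the averaged knockdown comparison the 1 raised list was called with 0 others, and a log2 shift of −0.2 planted in 867 genes with 1 7-mer, among 10904 genes, ranked 1 and was recovered as −0.15, so the search understated the planted effect.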

Results

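RNA-seq gene counts were measured in cultured mouse erythroblasts, the nucleated precursors of red blood cells, grown from fetal liver and labelled as lacking the tumour suppressor p53. The cells carried 1 of 3 short hairpin RNAs: a control hairpin, or hairpin 1 or hairpin 2 against Tis7, the older name of Ifrd1, which encodes an interferon-related regulator of transcription. Cells of each kind were exposed to tunicamycin at 2.5 µg/ml for 0, 4 or 8 h. Tunicamycin blocks the start of N-linked glycosylation and is used to load the endoplasmic reticulum (ER) with unfolded protein. Each of the 9 groups of hairpin and time held 2 libraries, A and B, which made 18 libraries. The labels do not say whether the A and B libraries came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

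Total counts of libraries A and B were 21174771 and 21325197 in control cells at 0 h, 19363777 and 19939082 at 4 h, and 20246755 and 17361812 at 8 h. With hairpin 1 they were 19999008 and 20095208 at 0 h, 18835072 and 20039994 at 4 h, and 17602646 and 18433150 at 8 h. With hairpin 2 they were 19601289 and 17765129 at 0 h, 18360934 and 18523648 at 4 h, and 16540598 and 16684226 at 8 h. Of 52550 genes, 12823 had enough counts to test, and the coefficient of biological variation shared by these genes was 0.139. Changes below are log2 fold changes ± the standard error of the edgeR fit, from groups of n = 2 libraries. A gene is said to rise, fall or change where its Benjamini-Hochberg adjusted p from edgeR's quasi-likelihood test was under 0.05 over all tested genes. Genes named for the size of their change between times or between hairpins had every library of one side above every library of the other.

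Ifrd1 (ENSMUSG00000001627; GRCm38 chromosome 12, 40201567 to 40248504, minus strand), the gene both hairpins target, was measured in every library before anything else. In control cells it stood at 48.6 and 54.5 CPM at 0 h, where CPM is a gene's counts scaled to a common library size, 60 and 73.4 at 4 h, and 49.4 and 55.8 at 8 h. With hairpin 1 it stood at 3.4 and 3.34 CPM at 0 h, 3.85 and 4.17 at 4 h, and 2.61 and 3.91 at 8 h. With hairpin 2 the values were 6.67 and 7.11 CPM at 0 h, 7.32 and 8.5 at 4 h, and 4.8 and 7.48 at 8 h. The transcript left at 0 h was therefore 6.55% of control with hairpin 1 (95% interval of the fit 4.81 to 8.91) and 13.4% with hairpin 2 (10 to 17.9). Averaged over the times, Ifrd1 fell by 4 ± 0.12 with hairpin 1 and by 3.02 ± 0.11 with hairpin 2 on the log2 scale, and the difference between the hairpins was −0.98 ± 0.12 (edgeR adjusted p = 1.54e-05). Its relative Ifrd2 did not pass the test, at −0.03 ± 0.05. Tunicamycin did not change Ifrd1 detectably in control cells, at 0.37 ± 0.18 after 4 h (adjusted p = 0.238) and 0.03 ± 0.18 after 8 h (adjusted p = 0.92).

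**Figure D1:**
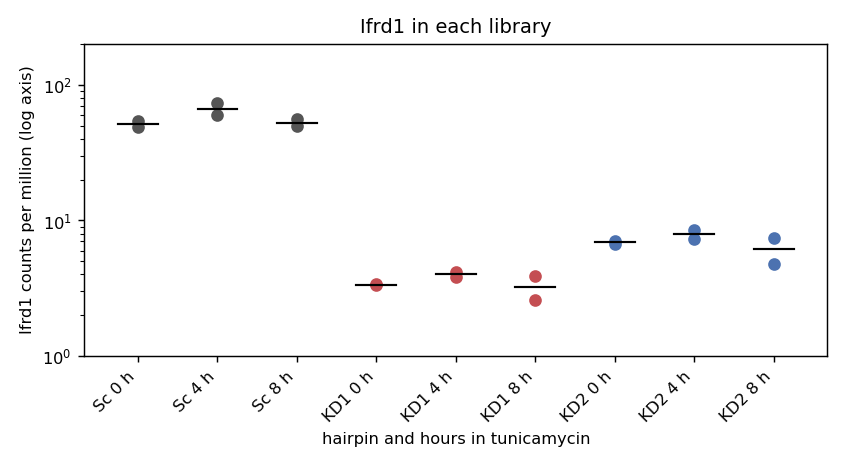
Ifrd1 in each library, in CPM on a log axis, against hours of tunicamycin; dots are the 2 libraries of a group and the black line is their mean. The 6 control libraries lie between 48.6 and 73.4, the hairpin 1 libraries between 2.61 and 4.17 and the hairpin 2 libraries between 4.8 and 8.5.

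The target sequences of the hairpins, each 21 nucleotides long, share 20. Hairpin 1 targets GCAGTACCACTTGCAGACAAA and hairpin 2 CAGTACCACTTGCAGACAAAT, starting at positions 1382 and 1383 of the 12-exon protein-coding transcript, inside the coding sequence. Both sites cross its junction of exons 10 and 11. They span 40204010 to 40204312 and 40204009 to 40204311 of chromosome 12 (GRCm38), intron included. The control hairpin has the target sequence CAACAAGATGAAGAGCACCAA. Trp53, the p53 gene, still gave counts in these cells, at 71.2 ± 1.64 CPM (SD, n = 2) in control cells at 0 h. Counts per gene do not show which exons were transcribed, so the genotype rests on the labels alone. Trp53 fell after 8 h of tunicamycin in control cells, by 1.18 ± 0.13, and was higher in knockdown than in control cells averaged over times, by 0.69 ± 0.06.

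The early response to tunicamycin was read from control cells at 4 h against 0 h. It was led by genes of the unfolded protein and amino acid stress responses. Derl3, a factor of ER-associated degradation, rose by 4.25 ± 0.48, Snhg12, a host transcript of small nucleolar RNAs, by 3.63 ± 0.17, and Nupr1, a stress-induced nuclear protein, by 3.56 ± 0.24. Trib3, a pseudokinase induced by CHOP, rose by 3.19 ± 0.16, and Ddit3, which encodes CHOP itself, by 2.94 ± 0.12, from 44 ± 1.81 to 337.4 ± 43.8 CPM (SD, n = 2). Cth, which makes cysteine, the peptide hormone gene Adm2, and Herpud1, of ER-associated degradation, rose by 2.62 ± 0.15, 2.6 ± 0.2 and 2.57 ± 0.12. The largest falls were those of the glycosyltransferase B3gnt7 at −2.13 ± 0.27, C2cd4a at −1.84 ± 0.39, Gp5, a platelet glycoprotein, at −1.67 ± 0.22, the cytokine signalling inhibitor Socs1 at −1.67 ± 0.26, and Phtf2 at −1.59 ± 0.14. Tnrc6a, of the microRNA silencing complex, Mat2a, which makes S-adenosylmethionine, and the fatty acid elongase Elovl6 fell by 1.59 ± 0.41, 1.58 ± 0.29 and 1.51 ± 0.18.

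Among the gene lists, ATF4-CHOP targets moved most together at 4 h: of 39 members, 31 rose and 0 fell (34 and 0 adjusted over the list alone). Its median change was 1.07 (camera adjusted p = 3.03e-43, and adjusted p = 9.05e-05 with an estimated correlation). Besides Ddit3, Trib3 and Cth, the amino acid transporter subunit Slc3a2 rose by 2.02 ± 0.12. Of 46 genes for ER chaperones and ER-associated degradation, 28 rose and 0 fell (32 and 1 adjusted over the list alone). The median over members was 0.61 (camera adjusted p = 3.2e-31, and adjusted p = 0.0041 with an estimated correlation). Hspa5, the main ER chaperone, rose by 2.49 ± 0.13, the disulfide isomerase Pdia4 by 2.15 ± 0.12 and Manf by 1.89 ± 0.1. The cytosolic tRNA synthetase list had 21 members, the tRNA exporter gene Xpot among them. Of these 8 rose and 0 fell (15 and 0 adjusted over the list alone). Cars rose by 0.78 ± 0.11, Nars by 0.73 ± 0.09, Tars by 0.71 ± 0.1 and Gars by 0.67 ± 0.1. That list's camera adjusted p was 3.88e-12, and its adjusted p = 0.122 with an estimated correlation.

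Cholesterol synthesis genes lay lower at 4 h: 6 of 26 fell and 0 rose (8 and 0 adjusted over the list alone). The list median was −0.33 (camera adjusted p = 0.00034, and adjusted p = 0.758 with an estimated correlation). Hmgcs1 fell by 1.44 ± 0.31, the low-density lipoprotein receptor gene Ldlr by 1.27 ± 0.27, Hsd17b7 by 1.02 ± 0.21 and Insig1 by 0.74 ± 0.18. Of 40 erythroid maturation and haem synthesis genes, 3 rose and 0 fell (3 and 0 adjusted over the list alone; camera adjusted p = 0.000628, and adjusted p = 0.758 with an estimated correlation). Gypa, the glycophorin A gene, rose by 0.73 ± 0.16. Of 22 immediate early genes 2 rose and 4 fell (2 and 4 adjusted over the list alone; camera adjusted p = 0.919). Atf3 rose by 1.74 ± 0.23, while the phosphatase genes Dusp6 and Dusp2 fell by 2.06 ± 0.24 and 2.05 ± 0.43. Of 22 listed p53 targets 2 rose and 2 fell (2 and 2 adjusted over the list alone; camera adjusted p = 0.919). The risen ones, Sesn2 and Bbc3, rose by 2.16 ± 0.18 and 1.78 ± 0.3, and both are also on the ATF4-CHOP list. In all, 1034 genes changed at 4 h, 494 higher and 540 lower, and 135 and 101 of these at least 2-fold. The count rested on each of the 4 libraries compared, since it fell to 425 and 491 without the 0 h libraries A and B and to 318 and 423 without the 4 h libraries A and B. Fitted on these 4 libraries alone it was 611. Bbc3, C2cd4a, Dusp2, Gypa, Hmgcs1, Hsd17b7, Insig1, Ldlr, Mat2a and Tnrc6a no longer passed without at least 1 of the 4 libraries.

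After 8 h the response in control cells was wider, with 5327 genes changed, 2655 higher and 2672 lower, and 1055 and 932 of these at least 2-fold. Derl3 rose by 8.03 ± 0.39, Snhg12 by 3.95 ± 0.17, Nupr1 by 3.75 ± 0.24, Ddit3 by 3.57 ± 0.13 and Trib3 by 3.48 ± 0.16. Dnajb9, an ER co-chaperone, and Ero1lb, an oxidase of ER disulfide bonds, rose by 3.49 ± 0.21 and 3.48 ± 0.19. Rn7sk, the 7SK RNA, which has no poly(A) tail, rose by 5.01 ± 0.67, as the share of counts from small non-coding RNA genes went from 0.069% and 0.085% of the 0 h libraries to 0.65% and 0.737% of the 8 h libraries. A single gene, Gm23935, carried most of that share, at 0.05% and 0.063% of counts at 0 h and 0.577% and 0.646% at 8 h. Elovl6 fell by 4.05 ± 0.21, Sdc1, the syndecan-1 gene, by 3.68 ± 0.25, C2cd4a by 2.99 ± 0.41, the tRNA methyltransferase gene Trmt61a by 2.89 ± 0.22 and Mat2a by 2.86 ± 0.31. The transcription factor gene Etv5, Parm1 and Gp5 fell by 2.82 ± 0.25, 2.68 ± 0.45 and 2.66 ± 0.24.

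ER chaperone and ER-associated degradation genes rose almost throughout at 8 h, 42 of 46 with 1 lower (43 and 1 adjusted over the list alone). Its median change was 1.62 (camera adjusted p = 1.04e-30, and adjusted p = 0.0042 with an estimated correlation). Hspa5 rose by 3.38 ± 0.13, Manf by 2.77 ± 0.1, the co-chaperone gene Dnajc3 by 2.76 ± 0.1 and Pdia6 by 2.62 ± 0.11. Of the ATF4-CHOP targets 35 rose and 2 fell (35 and 2 adjusted over the list alone). The median over members was 1.47 (camera adjusted p = 6.14e-18, and adjusted p = 0.00337 with an estimated correlation). Slc3a2 rose by 2.91 ± 0.12 and the glutathione-degrading enzyme gene Chac1 by 2.8 ± 0.16. Of the tRNA synthetase list 14 members rose and 3 fell (14 and 3 adjusted over the list alone; camera adjusted p = 0.0138, and adjusted p = 0.569 with an estimated correlation).

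Erythroid genes rose at 8 h, 27 of 40 with 0 lower (28 and 0 adjusted over the list alone). The list median was 0.8 (camera adjusted p = 6.31e-09, and adjusted p = 0.283 with an estimated correlation). Slc4a1, the band 3 anion exchanger, rose by 1.69 ± 0.18, Gypa by 1.63 ± 0.16, the haem enzyme gene Uros by 1.27 ± 0.14 and Mxi1, a MYC antagonist, by 1.2 ± 0.13. Of 26 cholesterol synthesis genes 20 fell and 1 rose (23 and 1 adjusted over the list alone). Its median change was −1.04 (camera adjusted p = 2.27e-08, and adjusted p = 0.283 with an estimated correlation). Acat2 fell by 2.47 ± 0.18, Lss by 1.83 ± 0.13, Dhcr24 by 1.65 ± 0.17 and Dhcr7 by 1.43 ± 0.15. Of 29 glycolysis and hypoxia genes 14 fell and 3 rose (15 and 3 adjusted over the list alone; camera adjusted p = 0.00142, and adjusted p = 0.283 with an estimated correlation). The lactate transporter gene Slc16a3 fell by 2.39 ± 0.17, Ldha, for lactate dehydrogenase, by 1.58 ± 0.15, Tpi1 by 1.53 ± 0.16 and Pfkl, a phosphofructokinase gene, by 1.21 ± 0.13. Of 35 cell cycle genes 15 fell and 2 rose (15 and 2 adjusted over the list alone; camera adjusted p = 0.0138, and adjusted p = 0.569 with an estimated correlation). Ccne1, for cyclin E1, fell by 1.39 ± 0.1 and the replication helicase gene Mcm3 by 1.04 ± 0.13.

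Interferon-response genes included 9 of 23 that rose at 8 h and 0 that fell (9 and 0 adjusted over the list alone; camera adjusted p = 0.0025, and adjusted p = 0.283 with an estimated correlation). Oasl2 rose by 2.17 ± 0.34, Irf7 by 2.06 ± 0.27, Oas3 by 1.95 ± 0.21 and Irf9 by 0.96 ± 0.12. Of 47 replication-dependent histone genes, whose transcripts mostly lack a poly(A) tail and whose copies share reads, 18 rose and 0 fell (18 and 0 adjusted over the list alone; camera adjusted p = 0.00138, and adjusted p = 0.283 with an estimated correlation), in libraries whose small non-coding share was also higher. The p53 targets went both ways, 8 higher and 8 lower (10 and 8 adjusted over the list alone), with Trp53inp1 at 2.99 ± 0.32 and the nuclease gene Aen at −2.45 ± 0.15, and the list did not pass (camera adjusted p = 0.562). Without single libraries the 8 h count ran from 3650 to 4389.

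From 4 h to 8 h, 3611 genes changed in control cells, 1762 higher and 1849 lower. The rises were led by Derl3 at 3.78 ± 0.26, Rn7sk at 3.67 ± 0.6, the interferon-induced gene Ifit1 at 2.26 ± 0.53, Trp53inp1 at 2.24 ± 0.3 and Arfgap3, of Golgi transport, at 1.93 ± 0.12. The falls were led by Elovl6 at −2.55 ± 0.21, Sdc1 at −2.34 ± 0.25, Trmt61a at −2.31 ± 0.22 and the corepressor gene Rcor2 at −2.13 ± 0.26. ER chaperone genes went on rising, 43 of 46 with 0 lower (45 and 1 adjusted over the list alone). The median over members was 0.87 (camera adjusted p = 3.66e-28, and adjusted p = 0.0115 with an estimated correlation). ATF4-CHOP targets moved less, 12 higher and 3 lower (14 and 3 adjusted over the list alone). The list median was 0.2 (camera adjusted p = 0.0305, and adjusted p = 0.431 with an estimated correlation). Of the erythroid genes 25 rose and 1 fell (27 and 1 adjusted over the list alone), with an adjusted p = 0.431 with an estimated correlation. The count was 1756 without the 8 h library B, and 2239 and 2372 without the 4 h libraries A and B. Ifit1 no longer passed without the 4 h library A or the 8 h library B.

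**Figure D2:**
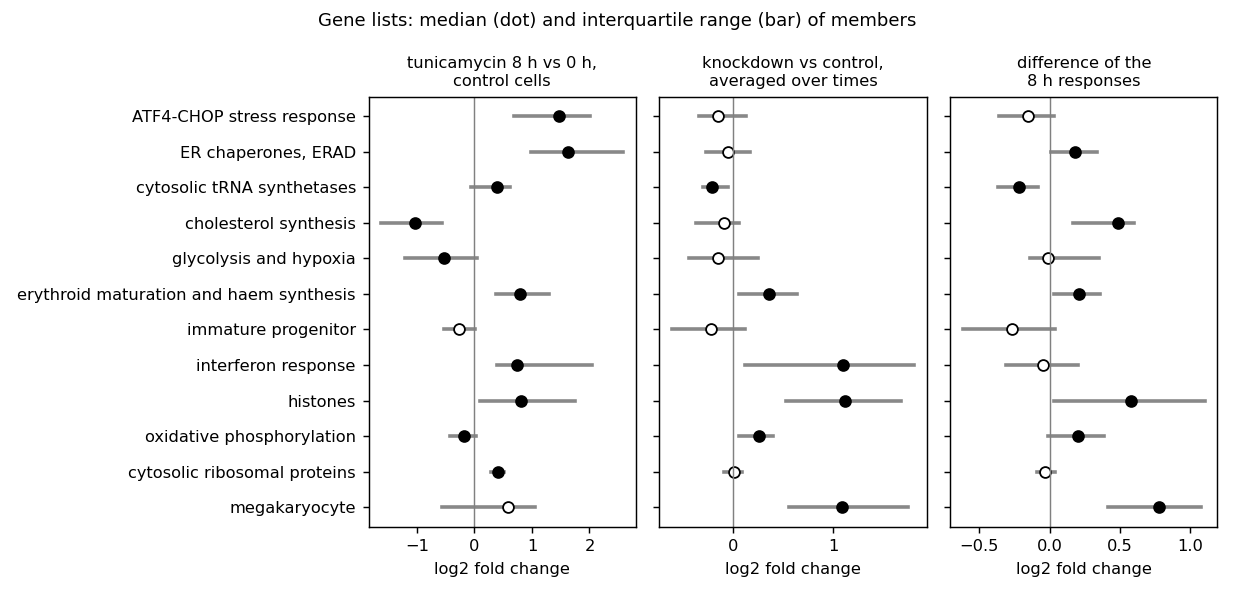
Change of 12 gene lists in 3 comparisons: tunicamycin for 8 h in control cells, knockdown against control averaged over times, and the difference of the 8 h tunicamycin response between knockdown and control. Dots are the median log2 fold change of a list's members, bars run from the lower to the upper quartile, and filled dots mark a camera adjusted p under 0.05 with the preset correlation; ER chaperone genes have a median of 1.62 at 8 h.

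Knockdown cells were compared with control cells as the mean of both hairpins against the control hairpin, at each time and averaged over the times. This comparison does not separate the loss of Ifrd1 from other effects that the hairpins share. In untreated knockdown cells the integrin gene Itgb4 was higher by 3.22 ± 0.29, and Itga2b, of the platelet integrin αIIb, by 2.02 ± 0.19. So were the butyrophilin gene Btn1a1 at 3.06 ± 0.34, the phospholipase gene Pla2g16 at 2.77 ± 0.23 and Irf7, a transcription factor of the interferon response, at 2.27 ± 0.25. Cox6b2, a cytochrome oxidase subunit gene, and Susd2 were higher by 2.55 ± 0.28 and 2.44 ± 0.33, and Rn7sk by 4.04 ± 0.63. Besides Ifrd1, the largest falls were those of the scramblase gene Plscr3 at −2.21 ± 0.12, Thy1, a surface glycoprotein, at −2.18 ± 0.14, Fam162a at −1.93 ± 0.18 and the growth factor gene Vegfb at −1.88 ± 0.12. The mitochondrial carrier gene Slc25a45 followed at −1.86 ± 0.14, Coro2a, an actin-binding protein, at −1.85 ± 0.2, and the deadenylase gene Parn at −1.84 ± 0.09. Of the genes named at 0 h for their size, Plscr3, Fam162a, Slc25a45 and Coro2a hold in their 3′ UTR GCAGACA or TGCAGAC, the pair of windows of the hairpin targets described with the hairpins below, while Thy1, Vegfb and Parn hold neither of these windows. At 0 h 2221 genes changed, 964 higher and 1257 lower. That count was 1077 and 1178 without the control libraries A and B, and 776 when only the 0 h libraries were fitted.

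Of 23 interferon-response genes 10 were higher and 1 lower at 0 h (14 and 1 adjusted over the list alone). Its median change was 0.86 (camera adjusted p = 2.77e-05, and adjusted p = 0.204 with an estimated correlation). Xaf1 was higher by 2.2 ± 0.33 and Oas3 by 1.3 ± 0.19, and Stat2 stood at −0.74 ± 0.18. Cholesterol synthesis genes were lower, 10 of 26 with 0 higher (10 and 0 adjusted over the list alone; camera adjusted p = 2.77e-05, and adjusted p = 0.674 with an estimated correlation). Tm7sf2 stood at −0.93 ± 0.13, Pmvk at −0.9 ± 0.09 and Dhcr7 at −0.65 ± 0.13. Erythroid genes were higher, 11 with 1 lower (15 and 1 adjusted over the list alone; camera adjusted p = 0.000552, and adjusted p = 0.799 with an estimated correlation), among them the haem synthesis genes Ppox at 0.79 ± 0.1, Urod at 0.69 ± 0.13, Uros at 0.66 ± 0.12 and Alad at 0.62 ± 0.11. Of the genes named here from lists, Stat2 and Dhcr7 hold GCAGACA. Stat2 and Uros no longer passed without control library A. Histone genes were higher, 13 with 1 lower (16 and 3 adjusted over the list alone; camera adjusted p = 0.000128, and adjusted p = 0.364 with an estimated correlation).

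At 4 h of tunicamycin 3387 genes differed between knockdown and control cells, 1537 higher and 1850 lower. Smtnl2 and the apolipoprotein gene Apol11b joined the largest rises, at 2.62 ± 0.38 and 2.35 ± 0.23, as did Rpph1, the RNA of ribonuclease P, which has no poly(A) tail, at 3.46 ± 0.74. Rexo2, a mitochondrial oligoribonuclease, and Ccdc6 joined the largest falls, at −1.97 ± 0.12 and −1.96 ± 0.27, and Plscr3 stood at −2.61 ± 0.13. ATF4-CHOP targets were lower in knockdown cells at this time, 18 of 39 with 3 higher (20 and 3 adjusted over the list alone). The median over members was −0.29 (camera adjusted p = 0.000424, and adjusted p = 0.174 with an estimated correlation). Ddit4 stood at −1.03 ± 0.18, the leucine transporter gene Slc7a5 at −1.01 ± 0.13, the proline synthesis gene Pycr1 at −0.77 ± 0.12 and Cth at −0.65 ± 0.12. Of the tRNA synthetase list 9 members were lower and 0 higher (9 and 0 adjusted over the list alone; camera adjusted p = 0.000343, and adjusted p = 0.628 with an estimated correlation). Sars stood at −0.71 ± 0.08 and the tRNA exporter gene Xpot at −0.62 ± 0.08. Among the genes named at 4 h, GCAGACA or TGCAGAC is held by Smtnl2 and Apol11b, which were higher, and by Plscr3, Rexo2, Ccdc6, Slc7a5 and Xpot, which were lower. Ddit4, Pycr1, Cth and Sars hold neither. Without the control libraries A or B at 4 h the count was 1582 or 1997, and Rpph1 no longer passed.

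At 8 h 4538 genes differed, 2142 higher and 2396 lower. Smtnl2 stood at 3.6 ± 0.36 and Susd2 at 2.87 ± 0.34, while Ntn4, the netrin 4 gene, Abcd2, a peroxisomal transporter gene, and Trnp1 stood at −2.57 ± 0.24, −2.41 ± 0.18 and −2.27 ± 0.14. Smtnl2, which was higher, and Ntn4, Abcd2 and Trnp1, which were lower, all hold GCAGACA. Megakaryocyte genes were higher, 7 of 8 with 0 lower (7 and 0 adjusted over the list alone). The list median was 1.67 (camera adjusted p = 2.55e-05, and adjusted p = 0.0227 with an estimated correlation). Itgb3, the integrin partner of Itga2b, stood at 2.28 ± 0.13, Itga2b at 1.77 ± 0.17, the platelet chemokine gene Pf4 at 1.73 ± 0.26 and Plek, for pleckstrin, at 1 ± 0.13. Of 78 nuclear-encoded oxidative phosphorylation genes 40 were higher and 4 lower (43 and 4 adjusted over the list alone; camera adjusted p = 2.01e-07, and adjusted p = 0.598 with an estimated correlation), and of 22 genes of the NRF2 oxidative stress response 9 were higher and 2 lower (12 and 2 adjusted over the list alone; camera adjusted p = 0.00252, and adjusted p = 0.435 with an estimated correlation). Without the control library A at 8 h the count was 2800.

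Averaged over the times, 6344 genes differed between knockdown and control cells, 3077 higher and 3267 lower, and 654 and 358 of these at least 2-fold. Btn1a1 was higher by 3.12 ± 0.19, Itgb4 by 2.88 ± 0.17, Pla2g16 by 2.8 ± 0.13, Smtnl2 by 2.66 ± 0.21, Cox6b2 by 2.59 ± 0.16 and Susd2 by 2.51 ± 0.19. Vegfb was lower, at −2.2 ± 0.07, with Thy1 at −2.18 ± 0.08, Plscr3 at −2.16 ± 0.07, Fam162a at −2.1 ± 0.11, Parn at −2.01 ± 0.05, Coro2a at −2 ± 0.12 and Ntn4 at −1.94 ± 0.14. Megakaryocyte genes were higher, 7 of 8 with 0 lower (7 and 1 adjusted over the list alone). Its median change was 1.09 (camera adjusted p = 3e-04, and adjusted p = 0.0603 with an estimated correlation). Itga2b stood at 1.85 ± 0.1, Itgb3 at 1.72 ± 0.07, Pf4 at 1.21 ± 0.16 and Plek at 0.56 ± 0.07. Of the interferon-response genes 16 were higher and 2 lower (16 and 2 adjusted over the list alone). The median over members was 1.1 (camera adjusted p = 0.000107, and adjusted p = 0.197 with an estimated correlation). Gbp3 stood at 3.37 ± 0.37, Xaf1 at 2.27 ± 0.19, Irf7 at 1.88 ± 0.13 and Oas3 at 1.1 ± 0.11. In the list of immature progenitor genes 7 of 14 were lower and 1 higher (7 and 1 adjusted over the list alone). Among them Spi1, for PU.1, stood at −0.99 ± 0.07 and the stem cell factor receptor gene Kit at −0.59 ± 0.09. The list did not pass (camera adjusted p = 0.0738). The progenitor and megakaryocyte lists also differed between the hairpins, as described below.

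Erythroid genes were higher over the times, 22 of 40 with 5 lower (22 and 5 adjusted over the list alone; camera adjusted p = 3e-04, and adjusted p = 0.544 with an estimated correlation), with the transferrin receptor gene Tfrc at 0.96 ± 0.08, Ppox at 0.92 ± 0.06 and Urod at 0.83 ± 0.07. Oxidative phosphorylation genes were higher, 49 of 78 with 5 lower (53 and 5 adjusted over the list alone; camera adjusted p = 3.31e-06, and adjusted p = 0.611 with an estimated correlation). Ndufa5 stood at 0.84 ± 0.07 and Ndufb4 at 0.68 ± 0.08, both of complex I. The genes of the tRNA synthetase list were lower, 10 of 21 with 0 higher (10 and 0 adjusted over the list alone; camera adjusted p = 0.00176, and adjusted p = 0.544 with an estimated correlation). Iars stood at −0.62 ± 0.06, Sars at −0.61 ± 0.05 and Mars at −0.42 ± 0.04. Histone genes were higher, 35 of 47 with 3 lower (36 and 3 adjusted over the list alone; camera adjusted p = 2e-06, and adjusted p = 0.197 with an estimated correlation). Hist1h4d stood at 2.38 ± 0.19 and Hist1h4c at 1.93 ± 0.18. The erythroid and histone lists stood lower with hairpin 1 than with hairpin 2, as described below. Their averages thus do not stand for each hairpin alone. Rn7sk and Rpph1 were higher by 4.03 ± 0.33 and 3.27 ± 0.43, and at 8 h the small non-coding share was 2.405% and 2.433% of counts with hairpin 1 and 2.938% and 1.707% with hairpin 2, against 0.65% and 0.737% in control cells. Of these shares Gm23935 alone made 1.974% and 1.895% with hairpin 1, 1.812% and 1.206% with hairpin 2 and 0.577% and 0.646% in control cells.

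Apart from the megakaryocyte genes, whose list passed with the preset correlation but not with an estimated one (adjusted p = 0.0603), markers of other cell types did not pass as lists in the averaged comparison. Of 10 mast cell and basophil genes 4 were higher and 4 lower (4 and 4 adjusted over the list alone), with the protease genes Mcpt4 at 3.16 ± 0.33 and Mcpt1 at 1.36 ± 0.16 and the IgE receptor subunit gene Ms4a2 at −1.34 ± 0.08. Macrophage genes had 2 of 4 higher and 0 lower (2 and 0 adjusted over the list alone), lymphocyte genes 1 of 4 higher, stroma and endothelium genes 1 of 3 higher, and granulocyte and hepatocyte genes 0 of 3 changed, with no camera adjusted p under 0.05. Of 16 genes of the SIN3-histone deacetylase complexes 4 were higher and 3 lower (4 and 2 adjusted over the list alone; camera adjusted p = 0.852), with Brms1, which holds GCAGACA, at −0.72 ± 0.06. Library B with hairpin 1 at 8 h and the 3 B libraries with hairpin 2 also held transcripts of other tissues, such as kidney markers at 31.3 CPM against 0.141 in control libraries. Without these 4 libraries the averaged comparison called 5691 genes, and of the 12655 genes tested both ways 6323 were called with them, 5655 without them and 5433 both times.

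The hairpins differed from the control in part through the same genes. Hairpin 1 changed 5124 genes and hairpin 2 changed 6897, of which 3427 went the same way with both, 1648 higher and 1779 lower, and 309 opposite ways. With hairpin 1 Itgb4 was higher by 4.16 ± 0.18 and Btnl10 by 2.16 ± 0.16, while Plscr3 fell by 2.45 ± 0.09, the vesicle coat gene Sec23a by 1.93 ± 0.09, the surface glycoprotein gene Bsg by 1.8 ± 0.08 and Gapt by 1.77 ± 0.1. With hairpin 2 Btn1a1 was higher by 3.93 ± 0.2, Smtnl2 by 3.32 ± 0.23 and Reln, for the matrix protein reelin, by 2.77 ± 0.11, while Coro2a fell by 2.98 ± 0.16, Thy1 by 2.82 ± 0.11, Vegfb by 2.76 ± 0.1 and Myo1g, a myosin of blood cells, by 2.5 ± 0.08. GCAGACA or TGCAGAC is held by Btnl10 and Smtnl2 among these rises and by Plscr3, Sec23a, Bsg, Coro2a and Myo1g among these falls. Megakaryocyte genes were higher with hairpin 2, 7 of 8 with 0 lower (7 and 0 adjusted over the list alone). The list median was 1.18 (camera adjusted p = 0.000193, and adjusted p = 0.0476 with an estimated correlation). With hairpin 1 ATF4-CHOP targets were lower, 22 of 39 with 3 higher (23 and 4 adjusted over the list alone; camera adjusted p = 0.00119, and adjusted p = 0.219 with an estimated correlation).

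Both comparisons used the same 6 control libraries, so their fold changes correlate even with no effect at all. In 20 simulations of unchanged groups against shared controls the mean number of genes called the same way was 0 and the correlation of fold changes 0.482, where the observed correlation across genes was 0.729. The covariance was 0.465 observed and 0.0319 simulated, a difference of 0.433. Independent lists of these sizes would share 664.4 higher and 713.5 lower genes. With hairpin 1 set against the A control libraries and hairpin 2 against the B control libraries 2388 genes were shared. The other way round 2084 were shared. Neither the simulation nor this split covers a deviation that all control libraries share. The simulated spread came only from the libraries within groups.

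**Figure D3:**
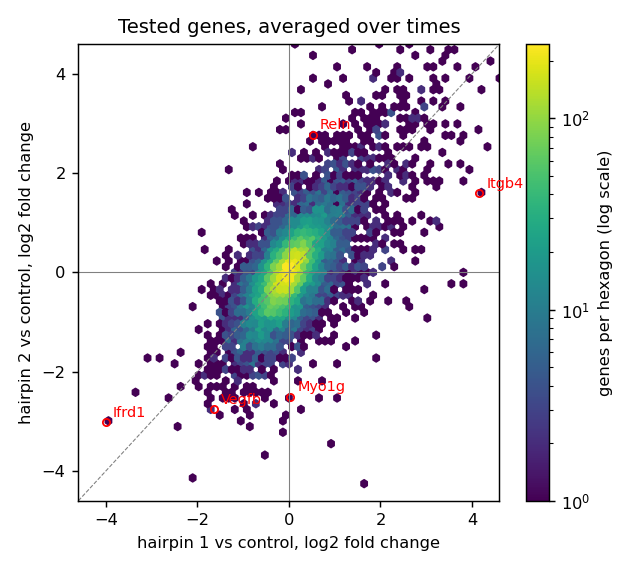
Log2 fold change of each tested gene against control averaged over times, with hairpin 1 on the horizontal and hairpin 2 on the vertical axis; shading gives the number of genes per hexagon, the dashed line marks equal change, and Ifrd1, Itgb4, Vegfb, Myo1g and Reln are marked. Of the tested genes 12691 lie inside the axes and 132 beyond them; Reln stands at 2.77 ± 0.11 with hairpin 2 and Myo1g at −2.5 ± 0.08.

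Set against each other, the hairpins differed in 5382 genes, 2691 higher and 2691 lower with hairpin 1, and 457 and 340 of these at least 2-fold. Itgb4 was higher with hairpin 1 by 2.57 ± 0.16, Myo1g by 2.54 ± 0.08, Coro2a by 1.97 ± 0.16, the prostaglandin-degrading enzyme gene Hpgd by 1.89 ± 0.31, Tep1, a telomerase-associated protein, by 1.86 ± 0.08, Casc4 by 1.81 ± 0.12 and the nucleoside transporter gene Slc28a2 by 1.75 ± 0.11. On the lower side with hairpin 1, Reln stood at −2.25 ± 0.1, the thiamine transporter gene Slc19a2 at −1.86 ± 0.08 and mt-Rnr2, the large mitochondrial ribosomal RNA, at −1.83 ± 0.16. Mst1 stood at −1.81 ± 0.11, Ecm1 at −1.73 ± 0.12 and Uba7, of the ISG15 conjugation pathway, at −1.72 ± 0.09. Coro2a, Myo1g and Casc4, on the higher side, and Slc19a2, on the lower side, hold GCAGACA or TGCAGAC. Erythroid genes were lower with hairpin 1 than with hairpin 2, 28 of 40 with 2 higher (30 and 2 adjusted over the list alone; camera adjusted p = 3.55e-08, and adjusted p = 0.426 with an estimated correlation). Rhd, for a blood group protein, stood at −1.07 ± 0.1 and Uros at −0.97 ± 0.08. Histone genes were lower too, 30 of 47 with 0 higher (33 and 0 adjusted over the list alone), with adjusted p = 0.385 with an estimated correlation. Cholesterol synthesis genes were higher, 12 of 26 with 1 lower (12 and 1 adjusted over the list alone; camera adjusted p = 5.01e-05, and adjusted p = 0.429 with an estimated correlation). The immature progenitor genes Myb, Spi1 and Kit stood at 1.16 ± 0.1, 0.98 ± 0.09 and 0.9 ± 0.1, in a list with 8 of 14 higher and 2 lower (8 and 2 adjusted over the list alone; camera adjusted p = 0.0288, and adjusted p = 0.547 with an estimated correlation). Megakaryocyte genes were lower, 6 of 8 with 0 higher (6 and 0 adjusted over the list alone; camera adjusted p = 0.00361, and adjusted p = 0.216 with an estimated correlation). Itgb3 stood at −1.14 ± 0.08 and Itga2b at −0.7 ± 0.11.

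A hairpin guide can lower transcripts other than its target through a match of its seed, the nucleotides near its 5′ end, to the 3′ UTR. The 10904 tested genes with an annotated 3′ UTR were therefore searched for matches to 7-nucleotide windows of the targets, with windows next to the planned seed sites added after the data had been seen. Of these genes 2495, or 22.9%, held GCAGACA or TGCAGAC, windows of the sequence that both targets share. In knockdown against control cells averaged over times, 988 of them were lower and 395 higher, 39.6% and 15.8%, at a median of −0.13. Of 8409 genes without either window 24.7% were lower and 27.7% higher, at a median of 0.02. Among genes at least 2-fold lower, 147 held a window and 164 did not, and among those at least 2-fold higher 82 held one and 440 did not. Genes without these windows can still hold another window of the targets. Among the lists, with the same pair of windows, 0 of 8 megakaryocyte genes, 1 of 39 histone genes and 4 of 77 oxidative phosphorylation genes held one. So did 7 of 39 ATF4-CHOP targets, 4 of 21 genes of the tRNA synthetase list, 5 of 23 interferon-response genes and 11 of 40 erythroid genes. With p adjusted over these 8409 genes alone in place of all tested genes, 2348 were higher and 2098 lower in knockdown cells. Windows of the control hairpin's target lay on the other side: GAAGAGC had a z of 3.49 in knockdown against control, the highest but 2 of 14157 7-mers, and AGCACCA, its planned seed site, a z of 2.62, at percentile 99.46. Genes that hold them thus stood slightly higher in knockdown than in control cells, by 0.054 and 0.044 on average. AGCACCA also moved where the control hairpin was on both sides or on neither, with a z of 2.73 for tunicamycin at 8 h in control cells and −3.22 for hairpin 1 against hairpin 2, while GAAGAGC stood at −0.39 and −0.86 there. The other windows of that target within 5 nucleotides of the planned site had z from −1.19 to 1.97.

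**Figure D4:**
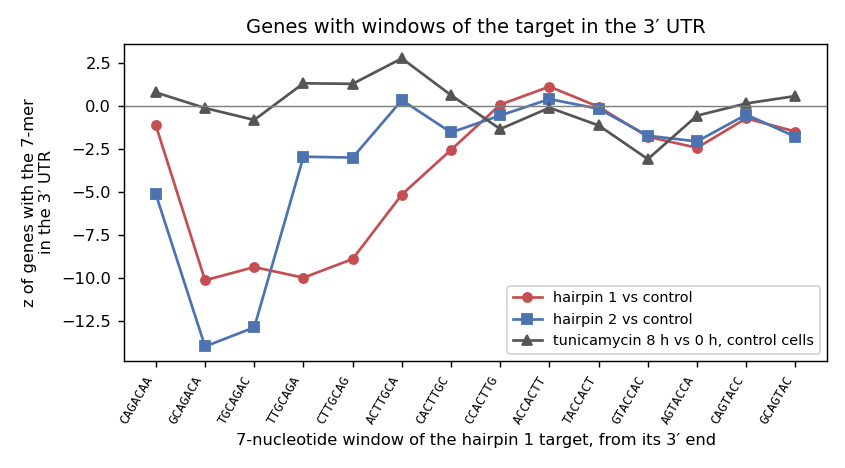
Effect of each 7-nucleotide window of the hairpin 1 target, by its position from the target's 3′ end, on genes that hold it in the 3′ UTR, given as z, the window's effect on log2 fold change over its standard error, in hairpin 1 and hairpin 2 cells against control and in tunicamycin-treated control cells. GCAGACA stands at −10.14 with hairpin 1, −13.99 with hairpin 2 and −0.12 with tunicamycin for 8 h.

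Whether knockdown cells answered tunicamycin differently was tested as the difference of the responses between knockdown and control cells. At 4 h the ATF4-CHOP list stood lower in this difference. Its median change was −0.24 (camera adjusted p = 6.92e-11, and adjusted p = 0.0193 with an estimated correlation), although 0 of its 39 members passed alone over all genes and 3 were lower and 0 higher adjusted over the list alone. Ddit3 stood at −0.64 ± 0.14 (edgeR adjusted p = 0.605), Trib3 at −0.64 ± 0.18 and Cth at −0.65 ± 0.18. In CPM, Ddit3 went from 44 ± 1.81 to 337.4 ± 43.8 in control cells, from 38.3 ± 3.88 to 236.6 ± 8.26 with hairpin 1 and from 72.7 ± 3.39 to 283.4 ± 4.24 with hairpin 2 (SD, n = 2 each). The tRNA synthetase list stood at −0.18 (camera adjusted p = 5.55e-06, and adjusted p = 0.536 with an estimated correlation), with 0 members past the threshold either way. Over all genes 0 passed in the difference of the 4 h responses by edgeR and 0 by DESeq2, with 468 at an unadjusted p under 0.05, fewer than the 5% of 12823 genes that would lie there by chance.

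At 8 h 92 genes differed in their response, 45 higher and 47 lower. Among those with the largest differences, Lars2, the mitochondrial leucyl-tRNA synthetase gene, stood at 1.46 ± 0.28, Gp5 at 1.33 ± 0.28, Itgb3 at 1.01 ± 0.17, the peroxiredoxin gene Prdx1 at 0.97 ± 0.17, Spred1, an inhibitor of Ras signalling, at 0.97 ± 0.18 and Gmppb, which makes GDP-mannose, at 0.94 ± 0.17. Coq8a, of coenzyme Q synthesis, stood at −1.52 ± 0.28, Snhg12 at −1.13 ± 0.2, the surface peptidase gene Dpp4 at −1.09 ± 0.17, the RNA helicase gene Ddx27 at −1.02 ± 0.17, Pdcd4 at −1.01 ± 0.19 and Ampd2, an AMP deaminase gene, at −1 ± 0.2. Of these genes Coq8a holds GCAGACA and TGCAGAC. Megakaryocyte genes stood higher as a list. The median over members was 0.78 (camera adjusted p = 4.61e-05, and adjusted p = 0.0275 with an estimated correlation), with 2 of 8 past the threshold and 0 lower (4 and 0 adjusted over the list alone). Itgb3 went from 26.8 ± 2.17 to 47.2 ± 3.92 CPM in control cells, from 43.1 ± 2.29 to 160 ± 6.06 with hairpin 1 and from 97.4 ± 3.42 to 328.2 ± 24.9 with hairpin 2 (SD, n = 2 each). Plek stood at 0.75 ± 0.17 (edgeR adjusted p = 0.0524). Cholesterol synthesis genes stood at a median of 0.49 with 0 of 26 past the threshold (8 higher and 0 lower adjusted over the list alone; camera adjusted p = 8.44e-08, and adjusted p = 0.369 with an estimated correlation), and histone genes at 0.58 with 0 of 47 past it (0 and 0 adjusted over the list alone; camera adjusted p = 3.67e-06, and adjusted p = 0.251 with an estimated correlation). ATF4-CHOP targets did not pass as a list at 8 h (camera adjusted p = 0.111).

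The count of 92 depended on single libraries. It was 0 without control library A or B at 0 h, control library B at 8 h, hairpin 1 library B at 8 h or hairpin 2 library A at 8 h, 2 without control library A at 8 h, 27 without hairpin 2 library B at 8 h, 55 without hairpin 2 library A at 0 h and 59 without hairpin 1 library A at 8 h. It was 2 without the 4 libraries that held transcripts of other tissues, and 245 with DESeq2. Each gene named here for its difference of the 8 h response fell short of the threshold without at least 1 library.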

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

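The tests of tissue reads and of the Ifrd1 knockdown as their source, of Rn7sk between the libraries of a group, of shifted seed windows in both patterns, and of the loss of Ifrd1 as the whole cause were chosen, as were the genes Rho and Kap, after the results were seen.

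By a direct test of the difference, the responses to tunicamycin differed between knockdown and control cells for 92 genes at 8 h. Among the lists fixed beforehand, 1 at 4 h and 1 at 8 h also passed with an estimated correlation. Neither was retested with a library left out, without the libraries that held transcripts of other tissues, or for each hairpin alone. A list of host genes of small nucleolar RNAs was chosen after the data had been seen and is described below. Its camera adjusted p at 4 h was 0.0232 with an estimated correlation, with 0 members past the threshold. That test is descriptive and adds no independent support. The ATF4-CHOP list had a median of −0.24 in the difference of the 4 h responses (camera adjusted p = 6.92e-11, and adjusted p = 0.0193 with an estimated correlation), while 0 of its 39 genes passed by edgeR, with Ddit3 at −0.64 ± 0.14, Trib3 at −0.64 ± 0.18 and Cth at −0.65 ± 0.18. Over all genes that comparison had 468 with an unadjusted p under 0.05, fewer than the 5% of 12823 that chance gives, and DESeq2 called 0. The megakaryocyte list had a median of 0.78 in the difference of the 8 h responses (camera adjusted p = 4.61e-05, and adjusted p = 0.0275 with an estimated correlation), with Itgb3 at 1.01 ± 0.17 and Gp5 at 1.33 ± 0.28. The genes past the threshold at 8 h included Prdx1 and Lars2, which were higher, and Snhg12 and Dpp4, which were lower. The count of 92 stood at 0 without control library A or B at 0 h, control library B at 8 h, hairpin 1 library B at 8 h or hairpin 2 library A at 8 h, and at 2 without control library A at 8 h. It was 27 without hairpin 2 library B at 8 h, 55 without hairpin 2 library A at 0 h, and 59 without hairpin 1 library A at 8 h. GCAGACA, a window of the hairpin targets, had the lowest z of 14157 7-mers in both differences. It stood at −4.22 at 4 h and −4.9 at 8 h. In the megakaryocyte list 0 of 8 genes held GCAGACA or TGCAGAC in the 3′ UTR. That argues against direct repression through these windows for that list. In the ATF4-CHOP list 7 of 39 genes held one, 17.9% against 22.9% of all genes searched. Whether the windows account for the ATF4-CHOP list or for single genes, or act indirectly, was not tested.

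Photoreceptor and kidney transcripts appeared in library B of hairpin 1 at 8 h and in the 3 B libraries of hairpin 2, where the labels name neither tissue. Kidney markers summed to 31.3 CPM in these 4 libraries, 0.362 in the other 8 knockdown libraries and 0.141 in control libraries, and photoreceptor markers to 27, 0.675 and 0.245. Rho, for rhodopsin, had 225 to 497 counts in the 4 libraries and 0 in the other 14, and the kidney gene Kap 131 to 186 and 0. The knockdown itself is excluded as the source, since the other 8 knockdown libraries held the kidney markers at 0.0116 of that level. Reads or RNA of other mouse tissue are a candidate source, with no sort or gate named in the labels: the 18 of 21 kidney markers silent or nearly silent in control libraries ranked alike in any 2 of the 4 libraries (lowest Spearman rho 0.907 across genes, which are not independent), and 476 genes seen mainly there made 0.0178% to 0.0306% of counts.

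RNAs without a poly(A) tail were higher in knockdown libraries. Rn7sk stood at 1.61 and 1.61 CPM in control libraries at 0 h and 50.5 and 53.8 at 8 h, against 624 and 799 with hairpin 1 and 568 and 561 with hairpin 2 at 8 h. The median difference of Rn7sk within groups was 0.358 in log2 (largest 1.61), 0.0889 of the knockdown difference of 4.03. That argues against carry-over that varies at random between the libraries of a group. Carry-over that varies between cultures or preparations cannot be excluded this way, since A and B may be technical repeats. A larger carry-over in all knockdown libraries may explain why these RNAs were higher. Of 11 other small non-coding genes 10 were higher, 4 of these past the threshold, and 1 was lower, with a lower quartile of 1.1. These 11 genes had low counts, with mean log2 CPM from −1.81 to 0.97. The best measured of them, Gm27605, stood at 0.25 ± 0.15 (edgeR adjusted p = 0.18). Gm26461 and Gm24514, counted as higher, had no standard error. Gm23935, which made most of the small non-coding share, is not among these genes. Mitochondrial ribosomal RNA was not higher in all knockdown libraries. At 0 h it made 0.079% and 0.105% of counts in control libraries, 0.031% and 0.047% with hairpin 1, and 0.107% and 0.168% with hairpin 2. A change in the cells' own small RNAs after the loss of Ifrd1 remains open and untested, and the histone genes share this limit.

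The hairpins differed from each other in 5382 genes, among them Itgb4, Myo1g and Reln, although their targets share 20 of 21 nucleotides, and 3427 genes changed the same way with both. The largest autosomal median difference, −0.036, argues against gain or loss of a whole autosome as the source, while changes of chromosome parts were not tested. In hairpin 1 cells against control the planned seed site of hairpin 1, CAGACAA, lay at percentile 14.37 of all 7-mers. In hairpin 2 cells against control the planned site of hairpin 2 lay at percentile 0.14. The target of hairpin 2 also holds CAGACAA, whose z was −5.13 in hairpin 2 cells against control and 4.85 between the hairpins. Windows shifted by 1 to 4 nucleotides may explain part of both patterns: GCAGACA had the lowest z of 14157 7-mers in knockdown against control, −13.24, where the lowest of 7-mers unrelated to the target was −3.9, which excludes the loss of Ifrd1 as the whole cause. Between the hairpins TTGCAGA had the lowest z, −6.09, and GCAGACA the highest, 7.58. Effects of Ifrd1 itself, which fell further with hairpin 1, repression by the control hairpin's own windows, which was not tested on its own (GAAGAGC at a z of 3.49, but AGCACCA also at −3.22 between hairpins 1 and 2), and other differences between the cell populations remain open for genes with and without these windows.

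Chance assignment of libraries was tested on 100 splits that mix hairpins within each time, the real one included. For knockdown against control averaged over times 1 split, the real one, reached its count of 6344, and the highest other gave 3289. Likewise 1 split, the real one, reached 5124 for hairpin 1 against control (highest other 3228), 6897 for hairpin 2 against control (highest other 5247) and 5382 between the hairpins (highest other 2427). Random assignment of single libraries thus did not reach these 4 counts in the splits drawn. The splits cannot test chance differences between the cell populations that carried the hairpins, since A and B may come from the same culture.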

How the results depend on the processing

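The omission of the 4 libraries with other-tissue reads and the count over genes without GCAGACA or TGCAGAC in the 3′ UTR were chosen after the data had been seen.

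Over 15 results and 234 alternatives, 204 stayed within 1.5 times the count or kept direction and side of the threshold, and 30 moved. Fitting only the compared groups gave 611 genes for tunicamycin at 4 h, 776 for knockdown at 0 h and 0 for the difference of the 8 h responses, but more genes than the fit of all groups for tunicamycin at 8 h against 4 h (4527 against 3611) and for knockdown at 4 h (3669 against 3387) and 8 h (5387 against 4538). The difference of the 8 h responses, with 92 genes, gave 245 with DESeq2, 256 without a filter on low counts, 201 with the replicate block, 2 without the 4 libraries (5691 for the averaged knockdown) and 59 over genes without those windows, which are fewer. The cause of the other moves was not tested. Gene list calls went from 104 to 10 with an estimated correlation and to 103 with the replicate block. The lists were not retested with libraries left out, so how far they depend on single libraries is not known. The letters A and B were not taken to pair the libraries. The reason was that deviations correlated above 0.1 in 20 of 36 pairs of groups but not in the others. The correlations had a median of 0.267 and ran from −0.642 to 0.795. Pairing by letter across the times of the same hairpin was not examined on its own. If libraries of the same letter share a culture, the averaged comparisons count more independent samples than there are. The replicate block raised the other counts of genes too, by less than 1.5 times, such as from 1034 to 1301 for tunicamycin at 4 h and from 2221 to 2636 for knockdown at 0 h, except that of the difference of the 4 h responses, which stayed at 0.

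With each library left out in turn, where the lone library left in a group is assumed to vary like the others, counts ran from 318 to 491 for tunicamycin at 4 h, 3650 to 4389 at 8 h and 1756 to 2989 at 8 h against 4 h. They ran from 1077 to 2167, 1582 to 3096 and 2800 to 4220 for knockdown at 0, 4 and 8 h, and 5560 to 6482 averaged. They ran from 4364 to 4929 for hairpin 1, 6269 to 6951 for hairpin 2, 4568 to 5301 between hairpins and 2941 to 3474 for genes changed the same way with both. The differences of responses gave 0 throughout at 4 h and 0 to 109 at 8 h. Ifrd1 ran from −3.56 to −3.46.

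Of 3590 values of named genes under alternatives 3436 kept direction and side, 146 lost and 5 gained the threshold, and 3 changed sign, none of them past it: Ifrd1 at 8 h of tunicamycin was −0.05 without control library A at 0 h and −0.05 without control library B at 8 h (−0.05 to 0.11 over left-out libraries, 0.11 without control library A at 8 h), and Ifrd2 in the averaged knockdown was 0 without the 4 libraries. With the simulated counts a 1.5-fold change in the difference of the 8 h responses was found in 10.4% of genes, so smaller differences are mostly out of reach.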

Other observations

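The 6 gene lists described here, and the genes named from them, were all chosen after the data had been seen, and their tests are descriptive.

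Ribosome biogenesis genes fell in control cells after 8 h of tunicamycin, 42 of 47 with 0 higher, at a median of −1.17 (camera adjusted p = 3.59e-21, and adjusted p = 0.0305 with an estimated correlation). Rrp1b fell by 2.41 ± 0.19, the RNA polymerase I subunit gene Polr1b by 2.07 ± 0.13, Nop16 by 1.88 ± 0.13 and Noc4l by 1.85 ± 0.13. At 4 h only 7 fell and 1 rose. Fatty acid synthesis genes fell at 8 h, 11 of 14 with 0 higher, at a median of −0.82 (adjusted p = 0.0305 with an estimated correlation). Fasn, for fatty acid synthase, fell by 2.24 ± 0.4, Acaca by 1.93 ± 0.26, Scd2 by 1.35 ± 0.14 and Acly by 1.09 ± 0.14. Of 35 genes of N-glycan synthesis and transfer 14 rose and 6 fell at 8 h (adjusted p = 0.318 with an estimated correlation). Alg12 rose by 2.18 ± 0.13, Gfpt1 by 1.15 ± 0.12, Stt3a by 1.04 ± 0.11 and Dpagt1, whose product tunicamycin blocks, by 0.68 ± 0.13. Of 37 proteasome genes 19 fell and 3 rose, and of 74 mitochondrial ribosome genes 43 fell and 1 rose, both with an adjusted p = 0.318 with an estimated correlation.

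Host genes of small nucleolar RNAs rose at 4 h of tunicamycin, 8 of 12 with 0 lower, at a median of 0.78 (adjusted p = 0.00529 with an estimated correlation). Snhg1 rose by 2.52 ± 0.12, Snhg5 by 1.85 ± 0.15, Zfas1 by 1.56 ± 0.13 and Gas5 by 0.8 ± 0.13. At 8 h 8 rose and 2 fell, at a median of 0.99 (adjusted p = 0.0746 with an estimated correlation). In knockdown against control averaged over times 9 of them were lower and 1 higher (adjusted p = 0.209 with an estimated correlation), with Snhg12 at −1.15 ± 0.08, Snhg5 at −0.78 ± 0.07, Zfas1 at −0.76 ± 0.06 and Snhg1 at −0.69 ± 0.06. In the difference of the 4 h responses their median was −0.31 (adjusted p = 0.0232 with an estimated correlation), with 0 past the threshold by edgeR, where 468 of all genes had an unadjusted p under 0.05, fewer than the 5% chance gives, and DESeq2 called 0. In the difference of the 8 h responses their median was −0.39, with 2 lower and 0 higher (adjusted p = 0.126 with an estimated correlation).

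Within the knockdown cells tunicamycin changed 833 genes at 4 h and 5932 at 8 h with hairpin 1, and 484 and 5604 with hairpin 2, against 1034 and 5327 in control cells. Such counts do not measure the size of a response and do not compare the responses directly. In the direct test of the difference between knockdown and control cells 0 genes passed at 4 h. At 8 h 92 passed, a count that depended on single libraries.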
